A study of Mus musculus with 8 samples.

How the data were processed

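Genomic DNA was extracted with phenol and chloroform from C57BL/6 mouse embryos, and PCR products were made into Illumina libraries, per the labels' protocols. Base editing uses a Cas9 protein that cuts at most 1 strand, fused to an enzyme that changes a base without a double-strand break; cytosine editors turn cytosine into thymine within a short window of the guide's site. The submitters' processing notes name Bowtie 0.12.2 and the genome builds mm8 and mm10 without saying what each was used for. How reads were trimmed, filtered, assigned to near-identical H3 copies or handled when they held insertions or deletions is not given in the sources used here.

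The deposited table holds 4160 lines, 1 for each of 26 sites, 20 positions and 8 libraries. Each line gives a read count, deposited as the whole number of reads with a base call at that position, and the percent of those reads with A, C, G and T, as deposited per position by the authors. The 4 percent values summed to 100 within 1e-06 on each line, and each percent times its count was within 0.01 of a whole number of reads, so converted reads were recovered as whole counts. No per-read values, insertions or deletions were used here. At 14 sites the lines run from position 20 to 1; read from 1 to 20 they give the guide-matched strand, and all bases are on that strand.

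Library names in the table were matched to the labels by their initials (W for wild type, CH for the group with changed Carm1 and H3) and by their number. All 12 pairs of replicates within a group differed far beyond sampling noise (smallest chi-square per degree of freedom 4680), so no pair holds the same counts deposited again. This does not show that the libraries came from separate embryos; each was counted as 1 replicate, with 4 per group, because the labels number them so.

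The value of a site was the percent of reads with T at its target cytosine. The target was position 5 at H3 sites, whose conversion changes the codon of arginine 17 (residues 13 to 18 of H3 are encoded on the opposite strand), and the mean of positions 6 and 7 at Carm1. At off-target sites it was the mean over cytosines at positions 4 to 8. These positions were chosen once the site sequences were known, while the tests, the alternatives and the rule for named sites were fixed before the data were examined. A minimum depth of 100 reads per site in each library removed no site, the smallest depth being 1228 and the largest 1226066 base calls. H3 off-target site 3 has no cytosine at positions 4 to 8 and entered only the test of all cytosines and the spectrum.

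Groups were compared with exact two-sided permutation tests of the difference in means over the 70 ordered splits of 8 libraries, whose smallest p is 0.0286, with Benjamini-Hochberg adjustment within the 9 H3 sites, the 15 off-target sites or the 12 base changes. The interval of a difference runs from the lowest edited minus the highest wild-type value to the highest edited minus the lowest wild-type value. Its nominal coverage of 97.1% under permutation holds only if the groups differ by a constant shift. Edited libraries varied far more at target sites (SD 7.12 against 0.00325 for the H3 mean), so the coverage there is not known. Shares of single libraries carry Wilson 95% intervals, whose half-width was at most 0.779 percentage points at target sites and 0.0291 at off-target sites. A count of 0 allows a share of up to 3 counts of the depth. At Carm1 and at off-target sites with several window cytosines, counts were summed over the cytosines, so the same read entered more than once. Intervals there are too narrow and floors too low. Reads from PCR without molecular identifiers are not independent molecules, so the intervals and floors of all sites cover counting error only.

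Counts of sites and cytosines were taken from limma 3.58.1 (R 4.3.3) on log2 odds with a pseudocount of 0.5, over 25 sites or 210 cytosines, at an adjusted p under 0.05. The script was tested on simulated data made from the wild-type shares and depths of the 210 cytosines: it recovered 0 of 20 cytosines changed 1.5-fold, 14 of 20 changed 2-fold and 18 of 20 changed 5-fold, with 1 false call among 150 unchanged. The simulation was a single draw and gave both groups and all cytosines the same noise, the median over cytosines in the wild-type libraries. It changed more cytosines than the 21 called in the real data, which eases the Benjamini-Hochberg threshold. Recovery of changed cytosines at off-target sites may therefore be lower than these rates. Edited libraries varied more at several target cytosines, so these rates do not describe those cytosines. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, biopython 1.88 and matplotlib 3.10.9.

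Each target site was named, as were the 3 off-target sites with the largest difference, since fewer than 3 passed the threshold, and the 10 cytosines with the largest difference. The H3 sites are named by number because the sources used here do not pair them with genes. Alternatives were no minimum depth or 1000 reads, any base other than the reference, the single cytosine with the highest share, a replicate block, leaving out each library in turn, pseudocounts of 1 and 0.1, a quasi-binomial model, limma on the share, sites above the median share, off-target positions alone and sums over reads. The spectrum took the mean share of each of the 12 base changes over all positions with that reference base.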

Results

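Genomic DNA of mouse embryos collected 19.5 days after microinjection was amplified and sequenced at 26 sites of 20 bases each in 8 libraries. The labels describe 4 libraries as wild type and 4 by both histidine in place of arginine 17 of histone H3 and loss of Carm1, the arginine methyltransferase known to methylate that residue; the second group is called edited here, and the labels do not say whether each embryo carried both changes. The sites comprised 9 H3 target sites, 1 Carm1 target site, and 16 off-target sites, of which 8 resembled the H3 site and 8 the Carm1 site. Positions were counted from 1 at the first base of the guide-matched strand, and every substitution is written with the reference base first. Median depth per site and library was 13407 to 61545 reads at the H3 target sites, 228715 to 410642 reads at the Carm1 target site, and 4775 to 1204590 reads at the off-target sites. Site coordinates, exons and the pairing of H3 sites with single H3 genes are not given in the sources used here. As background, the Carm1 gene lies on mouse chromosome 9, and the 12 replication-dependent H3 genes named in the reference table lie on chromosomes 13 and 3.

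The first comparison asked how completely the codon of H3 arginine 17 was converted at the target copies. Reads with thymine at position 5 (C5T), which changes the arginine 17 codon to histidine (R17H), made up 38.1% ± 7.12 (SD, n = 4) of reads in edited libraries, averaged over the 9 H3 target sites. The wild-type value was 0.0266% ± 0.00325 (n = 4). The difference was 38.1 percentage points, with a permutation interval of 30.2 to 47.4 at a nominal 97.1% coverage, which assumes a constant shift. The difference exceeded the spread between replicates (exact two-sided permutation p = 0.0286, the smallest that 4 libraries against 4 can give). Edited replicates 1 to 4 averaged 30.2%, 36.6%, 47.5% and 38.2%. The labels name embryos as the source but do not say that each replicate came from a separate embryo, so p-values measure the spread between these libraries.

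Conversion differed widely between the 9 H3 sites. H3 target sites 1, 3, 4, 5 and 8 had edited means of 42.9% ± 10.1, 46.6% ± 8.58, 46.6% ± 8.40, 46.6% ± 8.08 and 46.7% ± 8.23 (SD, n = 4). The near-equal values of sites 3, 4, 5 and 8 need not describe separate copies, as set out below. Among reads with a base call, sites 6 and 7 ranged from near-complete conversion to little. Site 6 was converted in 60.3%, 5.18%, 46.7% and 93.9% of reads in edited replicates 1 to 4, and site 7 in 16.02%, 85.8%, 96.5% and 2.27%. The Wilson 95% intervals for the extremes at site 7 were 96.2 to 96.8% and 2.07 to 2.49%, so counting error was far smaller than the differences between libraries. These intervals do not cover missing reads. Read depth at position 5 was 0.895 of the wild-type profile at site 6 in edited replicate 4. At site 7 it was 0.850 and 0.830 in edited replicates 2 and 3, so the high shares there leave out reads without a base call. Site 2 stayed at 2.49% ± 0.149 (n = 4) in edited libraries, and site 9 at 2.61%, 2.53% and 2.07% in replicates 1, 3 and 4 against 30.4% in replicate 2. In wild-type libraries, the mean at H3 target sites was at most 0.0320%.

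Each of the 9 H3 sites was higher in all 4 edited libraries than in all 4 wild-type libraries (exact permutation p = 0.0286, Benjamini-Hochberg adjusted p = 0.0286). At sites 6, 7 and 9 the call ended when any 1 wild-type library was left out, with adjusted permutation p of 0.0735, 0.193 and 0.371. With 3 wild-type libraries against 4 edited, a mixed split can give a larger difference in means than the real one, because the edited libraries differ widely. The loss of these calls therefore does not show dependence on any 1 wild-type library. Sites 1 to 8 share 1 sequence, CTTGCGCGGGGCCTTGCCGC. Of these, sites 3, 4, 5 and 8 had similar base composition at position 5 in each edited library (chi-square tests, lowest p = 0.0200 in replicate 4, adjusted p = 0.0801). They also matched in the change to adenine at position 5 in edited replicate 2 (7.52 to 7.83%) and at position 7 in edited replicate 4 (19.3 to 19.6%). How reads were divided among these sites is not given, so conversion of each single copy was not resolved, nor was its spread between libraries. Site 8 stood apart at other positions in edited replicate 2, with 2.15% T15A against at most 0.0213% at sites 3, 4 and 5. With these 4 sites counted once, the mean over 6 profiles was 33.9% ± 6.61 (n = 4) in edited libraries. Site 9 differs from the other 8 sites by G10A, and 4.26 to 6.68% of its reads carried A10G in the 8 libraries, edited and wild type alike.

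**Figure D1:**
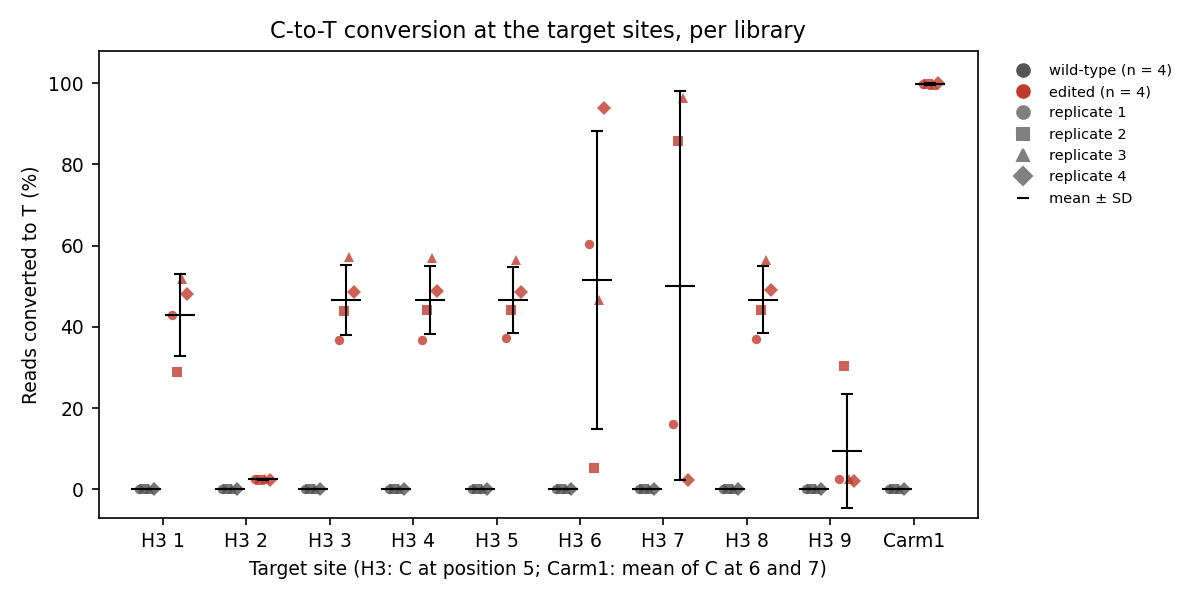
Share of reads converted to T (%, vertical axis) at the 9 H3 target sites (position 5) and the Carm1 target site (mean of positions 6 and 7), with a point for each library, its shape giving the replicate, and bars for the mean ± SD of 4 libraries. Edited libraries (red) lie at 99.5 to 99.96% at Carm1, spread from 2.27 to 96.5% at H3 site 7, and remain near 2.49% at H3 site 2, while wild-type libraries (grey) lie near 0 at each site.

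The neighbouring cytosine at position 7 was also converted at several H3 sites. C7T is synonymous, and it reached 89.5% of reads at site 7 and 53.6% at site 1 in edited replicate 2, above the 28.9% of C5T at site 1 in the same library. Read depth at these bases was 0.708 and 0.843 of the wild-type profile, so these shares cover only the reads with a base call. At sites 3, 4, 5 and 8 together, C7T averaged 0.107%, 3.49%, 2.26% and 13.6% in edited replicates 1 to 4, against at most 0.0216% in wild type. Changes of cytosine to other bases were present as well. C5A, which gives leucine in place of arginine 17 (R17L), averaged 1.56% ± 1.73 (n = 4) over the 9 sites against 0.00478% in wild type (exact permutation p = 0.0286, adjusted p = 0.0429 over 3 products), and reached 19.3% at site 6 in edited replicate 3. Its 9-site mean was 0.263%, 3.65%, 2.32% and 0.0143% in edited replicates 1 to 4 and fell to 0.865% without replicate 2. The C5A call ended when any 1 wild-type library was left out (adjusted permutation p = 0.257). With 3 wild-type libraries against 4 edited, a mixed split can give a larger difference than the real one, so this loss does not show dependence on a wild-type library. C5G, which gives proline (R17P), averaged 0.276% ± 0.540 against 0.00350% and did not pass (exact permutation p = 0.114, adjusted p = 0.114). Nearly all of it came from edited replicate 3, at 1.09%, and the mean without that library was 0.00646%. Without edited replicate 1 C5G passed (adjusted permutation p = 0.0286). These settings for C5A and C5G were chosen after seeing the data. C7A, synonymous, averaged 8.41% and 19.5% over sites 3, 4, 5 and 8 in edited replicates 1 and 4, and 0.0105% and 0.00175% in replicates 2 and 3.

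**Figure D2:**
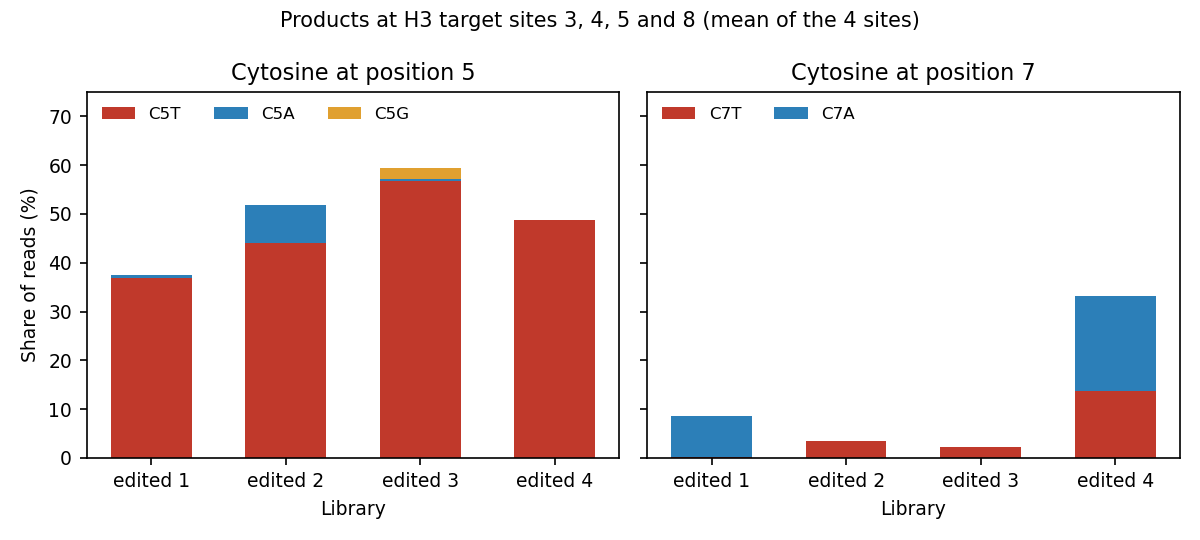
Share of reads (%, vertical axis) with each substitution at position 5 (left) and position 7 (right), averaged over H3 target sites 3, 4, 5 and 8, for each of the 4 edited libraries, with bars stacked by product. C5T makes up 36.9 to 56.8% of reads, while C5A reaches 7.69% in edited replicate 2 and C7A 19.5% in edited replicate 4.

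The second comparison asked the same of Carm1. Both target cytosines, C6T and C7T in AGGTACCAGCCATCCTTCCA, were converted in nearly all reads of each edited library: 99.8% ± 0.194 (SD, n = 4), against 0.0276% ± 0.0193 (n = 4) in wild type. The difference was 99.8 percentage points (permutation interval 99.5 to 99.9 at a nominal 97.1% coverage, exact permutation p = 0.0286). The lowest edited library, replicate 3, had 99.5% conversion (Wilson 95% interval 99.5 to 99.5%), and unconverted cytosine at position 6 ranged from 0.0245% in replicate 4 to 0.480% in replicate 3. On the listed strand the converted bases turn the triplet CAG at positions 7 to 9 into TAG, and on the opposite strand they turn TGG at positions 6 to 8 into TAA; both products are stop triplets, and the reading frame was not determined here. C10T at the same site was far lower, at 0.185% ± 0.0560 in edited against 0.0710% ± 0.0163 in wild type (limma adjusted p = 0.0204).

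The third comparison asked whether cytosines at similar sites elsewhere were converted. Off-target sites differed from their target by 3 bases (Carm1) or 4 bases (H3), and 15 of the 16 had a cytosine at positions 4 to 8. Over these 15 sites the mean C-to-T share was 0.0165% ± 0.00127 (n = 4) in edited and 0.0160% ± 0.000676 (n = 4) in wild-type libraries. The difference of 0.000504 percentage points (3.4e-05 without edited replicate 4) had an exact permutation interval of -0.00133 to 0.00265 and was within the spread between replicates (exact permutation p = 0.429). The Carm1-like sites averaged 0.0111% against 0.0104% (exact permutation p = 0.371), and the H3-like sites 0.0226% against 0.0223% (exact permutation p = 0.8).

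By the permutation test with Benjamini-Hochberg adjustment 0 of 15 off-target sites passed, with 1 at an unadjusted p under 0.05, while limma called 1 of 15 (3 unadjusted). An adjusted permutation value could pass here only if at least 9 of the 15 sites had the smallest possible p, so a single changed site could not pass. The 3 largest differences were at H3-like sites. H3 off-target site 2 had 0.0287% ± 0.00563 in edited and 0.0452% ± 0.0125 in wild type (n = 4 each, exact permutation adjusted p = 0.429), and the difference of -0.0165 percentage points was -0.0210 to -0.0109 with each library left out, nearest 0 without wild-type replicate 4. H3 off-target site 5 had 0.0191% ± 0.00789 against 0.00562% ± 0.00263 (exact permutation p = 0.0286, adjusted p = 0.429), was higher in 4 of 4 edited libraries, and was the site limma called (log2 difference 1.62, SE 0.35, adjusted p = 0.00443). That call depends on the cytosines averaged: limma called 0 off-target sites with the single highest cytosine of a site and 0 with all its cytosines, the latter setting chosen after seeing the data. In edited replicate 3 the share was 2 of 15488 base calls, or 0.0127%, under the floor of 0.0194%. Wild-type replicates 1, 2 and 4 were also under their floors, at 0.00956%, 0.00419% and 0.00453% against 0.0146%, 0.0128% and 0.00653%. These floors use base calls summed over positions 5, 6 and 7 and are therefore too low. The depth of this site was the lowest, so that the value rests on 16 converted of 86778 base calls in edited and 8 of 161210 in wild-type libraries, and its level lies within the 0.00624 to 0.0696% of the other 14 sites in edited libraries. H3 off-target site 4 had 0.0696% ± 0.0132 against 0.0649% ± 0.00441 (exact permutation adjusted p = 0.949), and without edited replicate 1 the difference became -0.00186 percentage points. With the 15 off-target sites fitted alone, limma called 2 sites, 1 higher and 1 lower.

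**Figure D3:**
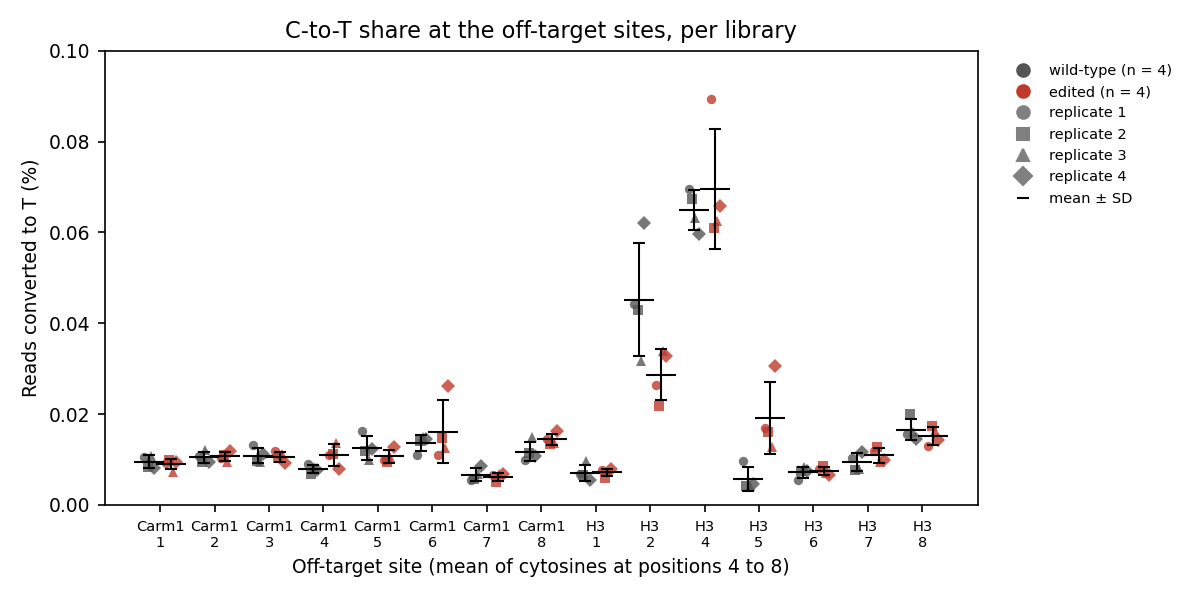
Share of reads converted to T (%, vertical axis from 0 to 0.1) at the 15 off-target sites with a cytosine at positions 4 to 8, with a point for each library and bars for the mean ± SD of 4 libraries per group. Edited (red) and wild-type (grey) libraries overlap at most sites, and the 3 largest differences are at H3 sites 2, 4 and 5.

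Across all 25 sites with a target or window cytosine, limma on log2 odds called 11 sites, all higher in edited libraries. These were the 9 H3 target sites, the Carm1 target site and H3 off-target site 5. With H3 sites 3, 4, 5 and 8 counted once, a setting chosen after seeing the data, limma called 8 of 22 sites. Log2 differences were 21.52 (SE 0.81) at Carm1 and 7.06 to 12.08 at the H3 sites. The same model over all 210 cytosines called 20 higher and 1 lower. C5T and C7T at sites 3, 4, 5 and 8 entered it separately, although these sites matched closely and may hold the same reads. The counts and rankings of cytosines given here may therefore hold repeats, and no cytosine count with these sites taken once was made. The 10 largest differences were C6T and C7T at Carm1, C5T at H3 sites 6, 7, 8, 4, 5, 3 and 1, and C7T at H3 site 7, where the edited mean was 30.3% ± 40.2 against 0.0238% (limma adjusted p = 0.0204). This mean fell to 10.6% without edited replicate 2, and the call ended without edited replicate 3 (adjusted p = 0.0629) or without any 1 wild-type library (adjusted p of up to 0.0677). All 20 higher cytosines were at target sites: besides these they were C5T at sites 9 and 2, C7T at sites 8, 5, 3, 4, 6, 2 and 9, and C10T at Carm1. These shares at sites 2, 6 and 9 were not separated here from reads of other H3 copies assigned to them. In edited replicate 4, C7A averaged 19.5% over sites 3, 4, 5 and 8 and was 1.03%, 1.26% and 0.576% at sites 1, 6 and 7. Low shares at sites 1, 6 and 7, such as the 2.27% C5T of site 7 in that library, were not separated from such reads either. At site 9, the A10G share times the C7T share of sites 3, 4, 5 and 8 was 0.00713%, 0.176%, 0.107% and 0.643% in edited replicates 1 to 4, against 0.0379%, 0.496%, 0.127% and 0.536% measured. C5T of 30.4% at site 9 in replicate 2 was 13.6 times its own such product. The lower one, chosen for mention after its values were seen, was position 16 of Carm1 off-target site 4, at 0.00621% against 0.0104% (limma adjusted p = 0.0201); this call ended without any 1 wild-type library (adjusted p of 0.0526 to 0.0677). The count of 21 fell to 12 without wild-type replicate 2 and to 12 without wild-type replicate 4, in each case with 12 at target sites. These 12 kept the call with each library left out: C6T and C7T at Carm1, C5T at the 9 H3 sites and C7T at H3 site 6. The other 8 higher cytosines, including C10T at Carm1, each lost it in at least 1 such setting. Leaving libraries out for single cytosines was chosen after seeing the data.

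The substitution spectrum over all 26 sites was dominated by C-to-T in edited libraries. The mean C-to-T share per cytosine was 2.98% ± 0.332 (n = 4) in edited against 0.0195% ± 0.000780 (n = 4) in wild-type libraries, and C-to-A and C-to-G were 0.229% ± 0.126 against 0.0138% and 0.0280% ± 0.0278 against 0.00312%. Each of the 3 had an exact permutation p of 0.0286 and an adjusted p of 0.114 over the 12 changes. Summed over reads, which gives the deeper off-target sites more weight, the differences were 0.991 percentage points for C-to-T, 0.0267 for C-to-A and 0.00274 for C-to-G, the last with an exact permutation p of 0.229. With this design the adjusted value could pass only if at least 7 of the 12 changes had the smallest possible p. G-to-A did not differ detectably (0.729% ± 0.634 against 1.03% ± 0.540, exact permutation p = 0.257, adjusted p = 0.771); most of it came from G4A and G19A at H3 sites 3, 4, 5 and 8, whose means over the 4 sites were 18.7 to 21.5% in 3 wild-type and 2 edited libraries and no more than 0.110% in the other 3. At positions of the off-target sites, C-to-T was 0.0197% ± 0.00158 in edited and 0.0180% ± 0.000605 in wild-type libraries (exact permutation p = 0.0571, adjusted p = 0.343).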

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

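The tests of explanations in this part were chosen after the values were seen. Of 50 groups of 4 libraries checked for a library far from the others, 4 held one, and chance gives about 1 in 20.

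H3 target site 9 had 30.4% C5T in edited replicate 2, far from the 2.07 to 2.61% of the other 3 edited libraries. Reads of other H3 copies assigned to site 9 would carry guanine at position 10. The A10G share times the C5T share at sites 3, 4, 5 and 8 gives the C5T expected from such reads if they came from those sites. That source is assumed, since sites 1, 2, 6 and 7 also carry guanine at position 10. In replicates 1, 3 and 4 observed over expected C5T averaged 0.966, so the 2 to 3% there may come from assigned reads, and at most 0.138 percentage points remained, which cannot be told apart from conversion of the site because the error of the expected share is not known. The same product for C7T in replicates 1, 3 and 4 was 0.00713%, 0.107% and 0.643%, against 0.0379%, 0.127% and 0.536% measured. For C7T the assumed source thus fell short in replicate 1. In replicate 2 the C5T ratio was 13.6, and A10G reads made up only 5.06%. This argues against assigned reads as the source of the 30.4% C5T. At H3 target site 2, with G19A as the marker of assigned reads in replicates 1 and 3, the ratio averaged 1.27 and up to 0.632 percentage points remained, so assigned reads and conversion of the site cannot be told apart there, and replicates 2 and 4 lack the marker.

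Read depth at positions 11 to 15 of H3 target site 9 in edited replicate 2 fell to 0.690 of the wild-type profile at its lowest, a signal in data not used in the comparisons. The mean over the 5 positions was 0.692, while positions 10 and 16 were at 0.997 and 1.001 and the other 7 libraries at 0.956 to 1.012, a pattern that could come from reads with a deletion. Depth was 0.692, 0.690 and 0.692 at positions 11, 14 and 15, which hold no cytosine. This argues against loss of base calls at converted cytosines. The C-to-T share at the cytosines between them, at most 0.0223%, covers only reads with a base call. The loss of 30.8% of reads is close to the 30.4% C5T of the same library, and whether the same reads carry both is not analysed here. The biological origin of such reads was not tested.

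Depth also fell to 0.626 of the wild-type profile at position 15 of H3 target site 1 in edited replicate 1. Among off-target sites, Carm1 off-target site 7 was lowest in edited replicate 2 (0.00494% against 0.00650 to 0.00678%), H3 off-target site 4 highest in edited replicate 1 (0.0893% against 0.0611 to 0.0657%), and H3 off-target site 5 highest in wild-type replicate 1 (0.00956% against 0.00419 to 0.00453%). The last value is 2 converted of 20530 base calls, under the floor of 0.0146%, and its Wilson 95% interval of 0.00267 to 0.0355% covers the other 3 libraries.

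Several substitutions at H3 target sites outside the intended one stood more than 10 times above the highest wild-type library. C13T, which is synonymous, reached 36.4% at site 9 in edited replicate 1, where C5T was 2.61%. C7T reached 89.5% at site 7 in edited replicate 2, and C7A reached 19.6% at site 5 in edited replicate 4. C5A reached 19.3% at site 6 and C5G 2.35% at site 5, both in edited replicate 3. At position 1, C1G, which gives asparagine in place of lysine 18 (K18N), reached 8.26% at site 1 and C1A, with the same product, 1.12% at site 5 in edited replicate 1, and C1T 1.90% at site 4 in edited replicate 3. T15A, which gives a stop codon in place of lysine 14 (K14*), reached 2.15% at site 8 in edited replicate 2. In that library it was 0.986% at site 6, 0.498% at site 7 and at most 0.0213% at sites 3, 4 and 5.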

How the results depend on the processing

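Settings that count missing reads, count 4 H3 sites once, use all cytosines, fit off-target sites alone or leave libraries out for C5A, C5G and single cytosines, and the block for the latter, were chosen after seeing the data. The H3 difference of 38.1 percentage points was 34.98 to 40.7 with each library left out (exact permutation p = 0.0286 each), 33.8 with sites 3, 4, 5 and 8 counted once, and 34.5 or 41.1 with reads missing at the base counted as unconverted or converted. The Carm1 difference was 99.7 to 99.9 with each library left out. With replicate number as a replicate block the differences were the same 38.1 and 99.8, but 4 pairs cannot give an exact permutation p below 0.125, so 0 of 9 H3 sites passed. Labels do not pair the numbers. Deviations from the group mean, in log odds of C-to-T at all cytosines, correlated at -0.246 to 0.0308 between same-numbered libraries. Between other pairs of a wild-type and an edited library they correlated at -0.181 to 0.245. Between 6 and 9 H3 sites passed with each library left out, and the losses came with 3 wild-type libraries, where the test is limited as stated above. The off-target mean difference was 3.4e-05 to 0.000917 with each library left out, and H3 off-target site 4 went from -0.00186 to 0.00754 and so changed sign; the cause was not tested. The count of 11 sites by limma was 11 to 13 with each library left out, 11 with the block, and 8 to 12 under the other settings that tested the target sites. Of the 10 target sites called in the main model, the quasi-binomial model called 8 and limma on the share called 7. The off-target count of 1 became 2 with any base, 0 with the single highest cytosine, 0 with all cytosines of a site, 2 with off-target sites alone, and 1 to 3 with each library left out (3 without wild-type replicate 3, 2 without edited replicate 4); the cause was not tested. The cytosine count of 21, with sites 3, 4, 5 and 8 entered separately, was 14 with the block and 12 to 21 with each library left out. The C-to-T spectrum difference of 2.96 was 2.85 to 3.1001 with each library left out, 0.991 summed over reads (C-to-A 0.0267, C-to-G 0.00274 with exact permutation p = 0.229), and 0.00172 at positions outside the target sites, which leave out the converted bases. Across single sites, cytosines and changes, 334 comparisons kept direction and side of the threshold, 79 lost the call, 1 gained it and 1 changed sign. Part of the 79 came from permutation tests with a wild-type library left out or with the replicate block, both limited as stated above. Tests of insertions and deletions, and gene-level count normalization and filtering, were not run, because the values used here are shares of reads at single positions. Depth limits H3 off-target site 5 most.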

Other observations

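The tests in this part were chosen after the values were seen.

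The edited libraries differed from one another in which H3 sites carried the histidine codon. In replicate 3 the 9-site mean was 47.5%, with 96.5% at site 7 and 2.53% at site 9, and in replicate 4 site 6 reached 93.9% while site 7 stayed at 2.27%. In replicate 2 the order was opposite, with 85.8% at site 7 and 5.18% at site 6. Any change at position 5 covered 66.3% of reads at site 6 in replicate 3, made up of 46.7% C5T, 19.3% C5A and 0.311% C5G. In the same 4 libraries the Carm1 site left at most 0.480% of cytosines at position 6 unconverted.

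Of the 35 splits of the 8 libraries into 4 and 4, 1 called as many as 11 sites, the real one, and the highest of the others called 0. For the 21 cytosines, again 1 of 35 splits called as many, and the highest of the others called 1. Every other split places converted and unconverted libraries in 1 group, which widens the spread at the target sites. Low counts in those splits were therefore set in advance by the target sites. The comparison does not test the weaker calls, such as H3 off-target site 5, C10T at Carm1 or position 16 of Carm1 off-target site 4.

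Averaged over H3 target sites 3, 4, 5 and 8, G4A and G19A lay at 18.7 to 21.5% in wild-type replicates 2, 3 and 4 and edited replicates 1 and 3, and at no more than 0.110% in the other 3 libraries. Base editing is argued against by the mean of 21.4% G19A in a wild-type library. Carry-over from edited into wild-type libraries is argued against by mean C5T over the same sites, at most 0.0302% in the 3 wild-type libraries, and carry-over from wild-type into edited libraries by mean C5T of 36.9% and 56.8% in replicates 1 and 3, where the reads it needs would leave at most 12.7% and 6.38%. Carry-over among wild-type libraries stays open, since their levels are alike (lowest over highest G19A 0.920). Within the 5 libraries the ratio of G4A to G19A was 1.0001 to 1.0056, which is consistent with both bases lying on 1 sequence variant of an H3 copy, whose inheritance was not tested.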
